A study of Mus musculus with 2 samples.

How the data were processed

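RNA of mouse gastrocnemius was sequenced as long reads in 2 libraries. Per the labels, each library was made from 2 µg of total RNA, with Ambion mix 1 (ERCC) and Lexogen spike-in RNAs added. The platform, the aligner and the versions of the authors' tools are not given in the sources used here. The deposited counts are raw, whole-number read counts per transcript model, 1 table per library, with no normalization and no pooling. Per the headers and notes of the deposited files, reads were aligned to mm10 and assigned by TALON, a program that groups long reads into transcript models, to GENCODE M21 transcripts or to models new to the library. Each deposited table lists models with at least 1 read and gives their length and class, and a deposited model file gives their exons. The classes are complete annotated, incomplete splice match, new combination of known splice sites (NIC), at least 1 new splice site (NNC), genomic, antisense and intergenic. Reads of 60 spike-in models were found, all of them ERCC models, and Lexogen spike-ins were not analysed here.

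The 2 libraries form 1 group, so no contrast between conditions exists, and replicate numbers were taken from the labels. All results come from 2 libraries of 1173957 and 626263 endogenous reads, in which 8845 and 5923 genes had at least 10 reads. Genes with any read numbered 25603 and 18646, or 20474 in replicate 1 thinned at random to the depth of replicate 2. Known genes numbered 15171 and 12907. A gene's reads were summed over all its models, CPM was taken over endogenous reads, and a count of 0 was read as an upper limit of 3 reads. Models assigned to no annotated gene, among them models antisense to a gene, were joined across libraries by overlap on the same strand. Reads shared between near-identical genes, such as a gene and its processed copies, were left where the deposited tables put them.

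Agreement was computed across genes with at least 1 read in either library on log2(CPM + 1). The biological coefficient of variation is the square root of the common dispersion of an intercept-only fit in edgeR 4.0.16 with TMM factors, over genes with at least 10 reads in both libraries together. Differences between the libraries were tested per gene on the same genes by a two-sided Fisher exact test of its reads against all other endogenous reads, with Benjamini-Hochberg adjustment, a threshold of 0.05 and at least 2-fold. Shares carry exact Clopper-Pearson 95% intervals. One gene was said to exceed another only where the exact interval of its share of their joint reads excluded 50% on the same side in both libraries.

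Cassette exon inclusion is the share of reads on models that hold an internal exon with both flanking splice sites, against models that join the flanking exons directly. Events needed at least 20 informative reads in each library and a minor form of at least 5% of them, a value set after the tables were seen but before inclusion was computed. The dominant transcript was taken among complete annotated and new-junction models in genes with at least 50 such reads in each library. New chains were matched by chromosome, strand and exact intron chain. For the length correction, the median log2 ratio of genes of similar read-weighted annotated transcript length was removed, over 20 length bins and genes with at least 50 reads, and an exact binomial test was used. Copies of Gapdh were found with minimap2 2.31 as other annotated genes, most of them processed pseudogenes, aligned over at least 900 nt at 95% identity or more.

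The rule for the genes named was fixed before the data were examined. It takes the 20 most abundant nuclear genes. From each fixed list it takes the 4 highest and the lowest member with at least 10 reads in each library, and every member of the myosin, troponin and myogenic regulator lists. It also takes the 10 called genes with the largest ratio between libraries and at least 50 reads in both together, the 10 new chains shared by the libraries with the highest mean CPM, and the cassette exons with the most reads plus those of named splicing targets. Dominant transcripts are named for the 10 genes with the most such reads and the 5 lowest shares. Some genes that the rule takes are not reported here. Lists covered contractile proteins, calcium handling, glycolysis, oxidative phosphorylation, mitochondrially encoded proteins, myogenic regulators, the neuromuscular junction, fibroblasts and matrix, tendon, endothelium, pericytes and smooth muscle, Schwann cells, immune cells, adipocytes, red blood cells, skin keratinocytes, cartilage and bone, imprinted growth genes, the cell cycle, ribosomal proteins, splicing regulators and non-coding RNAs. Gene pairs and list members with fewer reads that are given by name were chosen after their values were seen. A second list of 16 bone cell genes was drawn up after the bone genes had been noticed and before its members were looked up.

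The gene test was tested on simulated counts of the 2 libraries with 200 genes raised in a simulated library. On 9980 genes it called 100 of 100 genes raised 4-fold and 66 of 100 raised 2.5-fold, and it also called 52 of 9780 unchanged genes, because the raised genes took reads from the rest. With effective library sizes the counts were 100, 96 and 3. With no gene changed, 0 of 9973 genes were called. Simulated coefficients of variation of 0.2 and 0.4 were estimated as 0.196 on 9954 genes and 0.396 on 9820 genes. Of simulated cassette exons, 300 of 300 were found, with a median error of 1.27 percentage points in mean inclusion. These exons had more reads in each library than most measured events, and each gene had a clean pair of forms. The error therefore does not carry over to events with few reads. Alternatives covered the pseudocount, read minimums, normalization (TMM, DESeq2 1.42.0 size factors, library size), known genes, mitochondrially encoded genes, transcript classes, thinning, matching of chains and leaving out each library. Alternatives added after the data were seen were the length correction, minor forms of 1% and 10% and the fibroblast list without Col1a1. Work was done in R 4.3.3 and Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Parental alleles were not analysed here.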

Results

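Long-read RNA sequencing was carried out on gastrocnemius, the large calf muscle, from female mice at postnatal day 10. The animals were F1 hybrids of the C57BL/6J and CAST/EiJ strains. The labels give 2 libraries as biological replicates of 1 group and name no other condition, so no comparison between conditions was made, and the results describe this muscle and the spread between its libraries. Replicate 1 held 1207044 reads on 106000 transcript models and replicate 2 held 636063 reads on 56972. Without spike-ins, 1173957 and 626263 endogenous reads remained, so that 1 read was worth 0.852 and 1.597 CPM (read counts scaled to a common total). A gene without a read could lie at up to 2.56 CPM in replicate 1 and 4.79 CPM in replicate 2. Levels are means ± SD over the libraries (n = 2), and intervals and limits cover counting error only. The labels give both libraries the same donor identifier but number the females differently, so whether they come from separate animals is open. The SD and the tests on reads therefore measure only the spread between these 2 libraries, which may be technical.

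The most abundant transcripts came mainly from genes of contraction, calcium handling and energy supply. Acta1, which encodes skeletal muscle actin, was read at 79517 ± 20614 CPM, Atp2a1, which encodes the fast calcium pump of the sarcoplasmic reticulum, at 74258 ± 15429.9 CPM, and Ckm, which encodes muscle creatine kinase, at 52020.4 ± 19878 CPM. These 3 genes held 18.8% of endogenous reads in replicate 1 and 22.4% in replicate 2. The 20 most abundant nuclear genes held 35.1% and 38.3%. Tropomyosin 1 (Tpm1) followed at 19579.9 ± 2389 CPM, then fast troponin C (Tnnc2) at 18299 ± 5943 and the myosin genes Myh4, Mylpf and Myl1 at 14997 ± 8045, 13851 ± 2604 and 10705 ± 2988 CPM. Col3a1 and Col1a1, which encode fibrillar collagens, also ranked among the 20, at 9124 ± 6121 and 7915 ± 8175 CPM. Casq1, a calcium-storage protein of the sarcoplasmic reticulum, lay at 8776 ± 1012 CPM. The glycolytic genes Eno3, Aldoa, Ldha and Pkm lay at 8559 ± 2427, 8166 ± 1231, 7061 ± 1937 and 4501 ± 279 CPM. The remaining members were Slc25a4 at 8060.0 ± 2674, Actn3 at 6262 ± 359.6, Myh1 at 5593 ± 4346, Ak1 at 5004 ± 1369 and Mybpc2 at 4942 ± 1177 CPM. On mm10, Acta1 (ENSMUSG00000031972.5) lies on chromosome 8 from 123891769 to 123894751, Atp2a1 (ENSMUSG00000030730.12) on chromosome 7 from 126445858 to 126463108 and Ckm (ENSMUSG00000030399.2) on chromosome 7 from 19404776 to 19422841. With complete annotated models alone, Atp2a1 was at 12.4, Myh4 at 4621 and Aldoa at 4254 CPM, because most of their reads lay on models outside the annotation or incomplete.

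**Figure D1:**
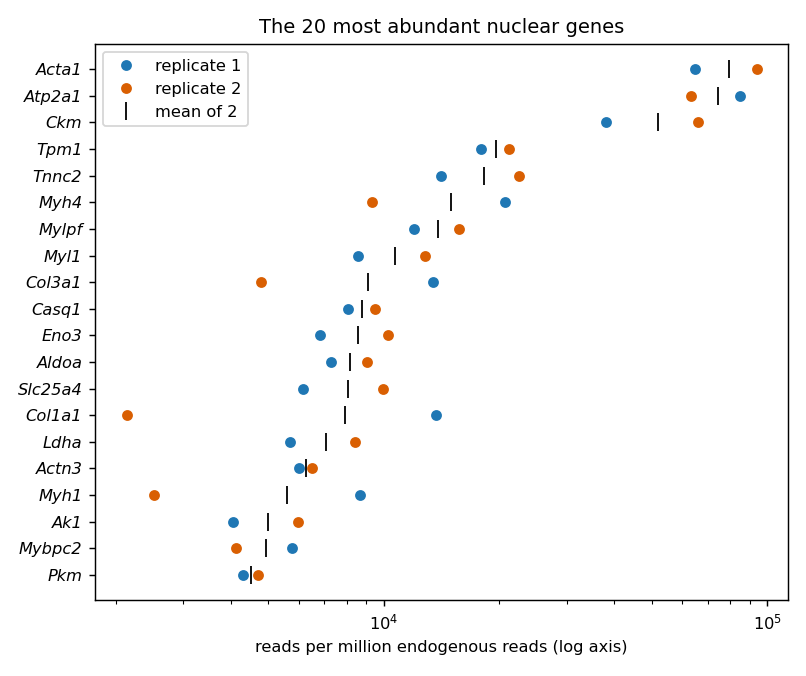
CPM over endogenous reads (log axis) of the 20 nuclear genes with the highest mean, with 1 point per library and a vertical tick at the mean of 2. Acta1, Atp2a1 and Ckm lead, and Col1a1 lies at 13696 CPM in replicate 1 and 2135 CPM in replicate 2.

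Among the sarcomeric myosin heavy chains, Myh4, the fast type 2B isoform, held the largest share of reads in both libraries, at 67.5% ± 6.89 (SD, n = 2). Myh1, the fast type 2X isoform, followed at 22.9% ± 4.71. The perinatal isoform Myh8 held 3.68% ± 1.497 (1.96% without incomplete splice matches), the slow isoform Myh7 2.89% ± 0.422, the type 2A isoform Myh2 2.498% ± 0.212 and the embryonic isoform Myh3 0.425% ± 0.0562. Shares were taken over 38744 and 8049 reads. Myh6 had 3 and 1 reads, Myh7b 3 and 0 and Myh13 1 and 1, and Myh15 had none, which allows a share of up to 0.00952% and 0.0458% (exact limits). Myh4 had 74.6% ± 5.81 of the joint reads of Myh4 and Myh1, Myh1 86.5% ± 2.47 of those of Myh1 and Myh8, and Myh2 85.5% ± 0.590 of those of Myh2 and Myh3, each above 50% in both libraries. The orders of Myh8 and Myh7 and of Myh7 and Myh2 were not resolved. With complete annotated models alone, Myh4 held 47.3% of the joint reads of Myh4 and Myh1, and Myh8 30.4% of those of Myh8 and Myh7. Both are means below 50%, and whether each library resolves these orders is not given here. In the same models Myh7 held 6.73% and Myh3 0.939% of all these reads. Gene pairs here and below were chosen after their values were seen.

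**Figure D2:**
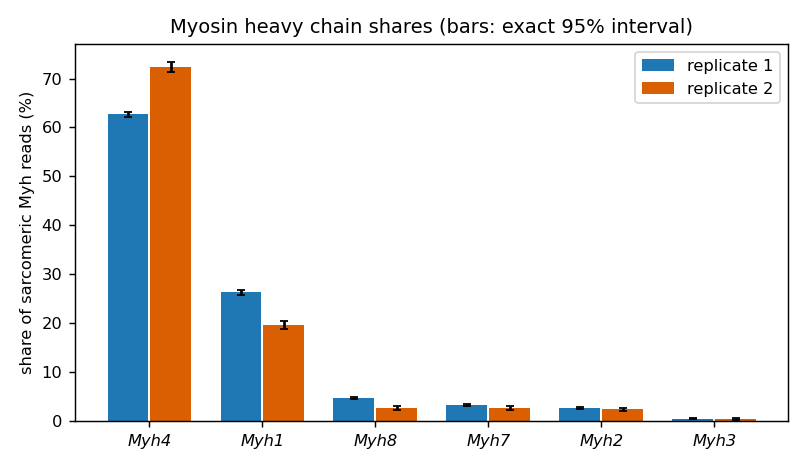
Share of sarcomeric myosin heavy chain reads (%) of the 6 genes with at least 10 reads in each library, with 1 bar per library and exact 95% intervals. Myh4 is highest in both libraries, at 62.7% in replicate 1 and 72.4% in replicate 2, followed by Myh1 at 26.3% and 19.6%.

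The libraries differed in these shares. Myh4 held 62.7% of the reads in replicate 1 (exact 95% interval 62.2 to 63.2) and 72.4% in replicate 2 (71.4 to 73.4). The Myh8 share was 4.74% and 2.62%. By two-sided Fisher exact tests adjusted over 10 genes, the shares differed for Myh4 (adjusted p = 7.91e-63), Myh1 (9.41e-37), Myh8 (1.32e-18) and Myh7 (0.0115), while Myh2 (0.266) and Myh3 (0.517) did not pass. In CPM, the summed list stood at 33003 and 12852 CPM in replicates 1 and 2, and 6 of 6 tested members were called higher in replicate 1, where called means both at least 2-fold apart and beyond counting error. In complete annotated models alone the list mean fell from 22928 to 11564 CPM. Longer transcripts took a larger share of replicate 1 in general, and after correction for length 2 of the 6, Myh1 and Myh8, were still called.

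Other contractile genes with fast and slow forms were read mostly as the fast form. The fast troponin genes Tnnc2, Tnni2 and Tnnt3 were read at 18299 ± 5943, 2193 ± 39.2 and 945 ± 332 CPM and held 96.9% ± 0.436 of troponin reads. The slow genes Tnnt1, Tnnc1 and Tnni1 lay at 292 ± 63.6, 256 ± 30.2 and 122 ± 0.322 CPM. The cardiac genes Tnnt2 and Tnni3 had 3 and 10 and 1 and 0 reads. The list sums were 17028 and 25847 CPM for the fast and 607 and 752 CPM for the slow and cardiac genes, and 0 of 3 and 1 of 4 tested members were called (Tnnt2, higher in replicate 2). The slow and cardiac mean fell from 679.7 to 347 CPM with complete annotated models alone. The light chain genes summed to 21657 and 29762 CPM, with 0 of 10 tested gene identifiers called. After Mylpf and Myl1 came Myl12a at 525 ± 122, Myl3 at 187 ± 8.93, Myl9 at 158 ± 35.9, Myl6 at 133 ± 14.9, Myl2 at 72.5 ± 14.4 and Myl4 at 34.5 ± 5.41 CPM. Myl12b is divided between 2 gene identifiers with 43 and 22 and with 7 and 3 reads, and is uncertain, while Myl6b had 3 and 0 reads. Mylpf held 99.46% ± 0.204 of the joint reads of Mylpf and the slow light chain gene Myl2.

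Actins and tropomyosins summed to 89656 and 122916 CPM, and 0 of 9 tested members were called. Acta1 held 98.3% ± 0.0167 of the joint reads of Acta1 and the cardiac actin gene Actc1, which lay at 1392 ± 348 CPM. Tpm2 was read at 3796 ± 159.5 CPM and Tpm4, the lowest of the list, at 194 ± 9.44. Among giant, Z-disc and M-band proteins, 19 of 20 genes had at least 10 reads in each library. Actn3 and Mybpc2 led, followed by the intermediate filament gene Des at 3912 ± 447 CPM and by Actn2 at 3101 ± 491, with Ankrd2 lowest of these 19, at 41.4 ± 6.56. This list summed to 28215 and 24124 CPM, and 2 of 20 members, Mybpc1 and Flnc, were called higher in replicate 1. After correction for length neither was still called. Mybpc1 fell short of 2-fold but stayed higher in replicate 1, at a log2 ratio of 0.715 (exact binomial test, adjusted p = 4.64e-28).

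Calcium handling was dominated by Atp2a1 and Casq1. The sarcolumenin gene Srl and the parvalbumin gene Pvalb followed at 3282 ± 967 and 1442 ± 345 CPM, and Sln was lowest of the members with at least 10 reads in each library, at 65.7 ± 10.98. Atp2a1 held 99.8% ± 0.0896 of the joint reads of Atp2a1 and Atp2a2, the slow and cardiac pump, Casq1 96.3% ± 1.02 of those of Casq1 and Casq2, and Ryr1 99.48% ± 0.729 of those of Ryr1 and Ryr3. With complete annotated models alone, the Atp2a1 share was 8.28%, since most Atp2a1 reads lay on splice chains outside the annotation. The list summed to 101810 and 80548 CPM, and its mean fell from 91179 to 16302 CPM in those models. Of 15 tested members, Cacna1s and Atp2a2 were called higher in replicate 1 and Hrc was called higher in replicate 2. Only Hrc of these was still called after correction for length. Cacna1s and Atp2a2 then fell short of 2-fold but stayed higher in replicate 1. Their log2 ratios were 0.856 and 0.737 (exact binomial test, adjusted p = 6.22e-09 and 0.00538).

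Genes of glycolysis and glycogen use summed to 73562 and 111408 CPM, and 0 of 17 tested members were called. After correction for length 1 member, Ckm, was called higher in replicate 2. Ckm, Eno3, Aldoa and Ldha led the list. Gapdh was lowest of those with at least 10 reads in each library, with 43 and 26 reads, but 67 copies of it, most of them processed pseudogenes, held 5149 and 2530 reads, so its level is uncertain. Eno3, the muscle enolase, held 90.6% ± 2.02 of the joint reads of Eno3 and Eno1, and Pgam2, the muscle phosphoglycerate mutase, 97.7% ± 1.24 of those of Pgam2 and Pgam1. Nuclear genes of oxidative phosphorylation summed to 22643 and 31557 CPM, with 0 of 22 members called. Slc25a4, the adenine nucleotide carrier, led, followed by Atp5b at 4349 ± 367, Atp5a1 at 2832 ± 37.0 and Cox4i1 at 1939 ± 699.8 CPM, with Cox6a1 lowest at 72.7 ± 10.1. The muscle forms Cox6a2 and Cox8b held 89.0% ± 0.192 and 64.2% ± 3.68 of the reads shared with Cox6a1 and Cox8a. Mitochondrially encoded genes took 0.0288% and 0.0557% of endogenous reads, and their protein-coding members summed to 286 and 548 CPM. How fully such RNAs were captured and counted was not tested, so their levels are uncertain. The cytochrome oxidase gene mt-Co1 led at 216 ± 89.8 CPM, followed by mt-Cytb at 78.5 ± 62.8, mt-Nd1 at 37.3 ± 8.20 and mt-Nd5 at 27.4 ± 10.99. Lowest of those with at least 10 reads in each library was mt-Atp6, at 14.6 ± 8.65. Of 8 tested, mt-Cytb was called higher in replicate 2.

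Myogenic regulators were read at lower levels, with a list sum of 1152 and 988 CPM and 0 of 10 tested members called. Myog, which drives terminal differentiation, lay at 299 ± 42.9 CPM, Mef2c at 269 ± 84.0, Mef2d at 122 ± 41.1 and Myf6 at 102 ± 30.3. Cdh15 lay at 62.9 ± 27.9, Mef2a at 59.0 ± 20.2, Mymk, which is needed for myoblast fusion, at 52.0 ± 3.55 and Myod1 at 44.5 ± 0.293 CPM. Ncam1 had 19 and 6 reads. The satellite cell factor Pax7 had 2 and 4 reads, Myf5 2 and 3, Mymx 7 and 1 and Pax3 none. Myog held 86.9% ± 1.56 of the joint reads of Myog and Myod1. Of the neuromuscular junction genes, which summed to 549 and 503 CPM, Chrna1 lay at 152 ± 8.78, Ache at 102 ± 36.2, Chrnb1 at 89.7 ± 4.05 and Rapsn at 69.6 ± 3.23 CPM. Dok7 was lowest of those with at least 10 reads in each library, at 33.2 ± 8.51, and 0 of 10 were called. The adult acetylcholine receptor subunit gene Chrne held 89.0% ± 4.06 of the joint reads of Chrne and the fetal subunit gene Chrng, which had 9 and 3 reads. With complete annotated models alone that share was 76.5% and was no longer resolved.

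Genes of fibroblasts and matrix were abundant and differed between the libraries. Their sum was 32362 and 10096 CPM in replicates 1 and 2, which is 3.21-fold higher in replicate 1, and 6 of 11 members were called higher there. Col3a1 and Col1a1 led, followed by Sparc at 1707 ± 314 and Col1a2 at 1158 ± 722 CPM, with Fbn1 lowest of those with at least 10 reads in each library, at 30.5 ± 16.0. The collagen genes Col1a1, Col3a1, Col1a2, Col6a1 and Col5a1 and the matrix gene Postn made up the 6. After correction for length Col1a1 and Postn were still called, while Col1a2 and Col6a1 had no length and were not retested. Col3a1 and Col5a1 then fell short of 2-fold but stayed higher in replicate 1. Their log2 ratios were 0.788 and 0.846 (exact binomial test, adjusted p = 2.04e-183 and 2.31e-05). The order of Col3a1 and Col1a1 was not resolved, and with complete annotated models alone Col3a1 held 63.4% of their joint reads and exceeded Col1a1 in both libraries. The members Dcn, Lum, Pdgfra, Sparc and Fbn1 were not called. Col1a1 is also the main collagen of bone, and without it the list stood at 18666 and 7962 CPM (2.34-fold). This alternative was chosen after the data were seen.

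Markers of other cell types in dissected muscle varied in level. Schwann cell genes summed to 1124 and 1032 CPM, of which the myelin genes Pmp22 and Mbp gave 515 ± 32.3 and 254 ± 13.4, and 0 of 8 tested members were called. Red blood cell genes summed to 762 and 468 CPM, led by the globin genes Hba-a1 at 321 ± 61.3, Hbb-bs at 171 ± 94.7, Hba-a2 at 72.8 ± 30.7 and Hbb-bt at 33.3 ± 13.2, which are near-identical in pairs and therefore uncertain. Of these Hbb-bs was called higher in replicate 1, and after correction for length Hbb-bs and Hba-a2 were. Endothelial genes summed to 512 and 369 CPM, with Cldn5 at 184 ± 16.6, Egfl7 at 78.9 ± 8.04, Pecam1 at 62.8 ± 25.6 and Cdh5 at 41.3 ± 20.0. Tendon genes summed to 436 and 369 CPM, with Fmod at 169.6 ± 27.6, Tnmd at 89.9 ± 0.618, Thbs4 at 67.4 ± 29.9, Scx at 47.5 ± 14.1 and Comp at 18.6 ± 1.43, and 0 of 6 were called. Pericyte and smooth muscle genes summed to 459 and 273 CPM, with Rgs5 at 189.7 ± 58.2, Kcnj8 at 52.5 ± 9.25, Abcc9 at 34.8 ± 26.7 and Pdgfrb at 33.0 ± 17.2. Immune genes summed to 199 and 136 CPM, with Csf1r at 37.5 ± 16.9, Lyz2 at 35.9 ± 3.39 and C1qa at 23.0 ± 3.61. The adipocyte list summed to 3196 and 2774 CPM, but most of it was Car3 at 2884 ± 263, which muscle fibres also express, ahead of Fabp4 at 69.1 ± 11.9. Skin keratinocyte genes had 8 and 5 reads in all. Called higher in replicate 1 were 2 of 8 endothelial genes (Tek and Kdr), 2 of 7 pericyte and smooth muscle genes (Abcc9 and Myh11) and 1 of 8 immune genes (Mrc1), none of them after correction for length.

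Genes of cartilage and bone were read almost entirely in replicate 1, with a sum of 214 and 14.4 CPM (14.9-fold). Ibsp, which encodes a bone matrix sialoprotein, had 114 and 0 reads, and Bglap, which encodes osteocalcin, 64 and 0. The osteocyte gene Dmp1 had 28 and 3 reads, and these 3 of 4 tested members were called. The cartilage collagen gene Col2a1 had 36 and 6 reads, Sp7 6 and 0, Col10a1 3 and 0 and Acan none. After correction for length Ibsp and Bglap were still called. Dmp1 did not pass (exact binomial test, adjusted p = 0.0988), though its log2 ratio was 1.90 against 2.12 before. Adjusted over the list alone, the counts of called genes equalled those over all genes for every list except fibroblast and matrix (8 in place of 6), pericyte and smooth muscle (4 in place of 2), imprinted growth genes (4 in place of 2), cartilage and bone (4 in place of 3), adipocyte (1 in place of 0) and a second list of bone cell genes drawn up later (3 in place of 2).

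Imprinted growth genes summed to 7224 and 6245 CPM. The non-coding RNA gene H19 lay at 3369.6 ± 294 CPM, the cell cycle inhibitor gene Cdkn1c at 1819 ± 3.53, Dlk1 at 471 ± 81.6 and Meg3 at 391 ± 273, with Igf2r lowest of those with at least 10 reads in each library, at 33.1 ± 21.9. Of 13 tested members Meg3 and Igf2r were called higher in replicate 1, and Meg3 was still called after correction for length. Genes of ribosomal proteins and translation factors summed to 6345 and 6430.2 CPM, led by Rplp0 at 1055 ± 136, Rpl4 at 668 ± 2.07, Eef2 at 506 ± 262 and Rpl13 at 419 ± 44.9, with Rps24 lowest at 96.1 ± 31.2. Of 21 members Eef2 was called, and not after correction for length. The order of Eef1a1 and Eef1a2, which replaces it in adult muscle, was not resolved.

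The spread between the libraries was far larger than sampling noise. Across genes, Pearson's r of log2(CPM + 1) was 0.886 and Spearman's rho 0.708 over 29282 genes, which are not independent replicates. Spearman's rho was 0.874 over genes with at least 10 reads and 0.903 over known genes. Over 9953 genes a chi-square of 72888 was found on 9952 degrees of freedom, 7.32 per degree, so the counts are not those of 1 library deposited again. The biological coefficient of variation was 0.261. By two-sided Fisher exact tests with Benjamini-Hochberg adjustment, 528 of 9953 genes (5.30%) were at least 2-fold apart and beyond counting error, 442 higher in replicate 1 and 86 in replicate 2. With effective library sizes from edgeR's TMM, 429 genes were called, 230 of them higher in replicate 1, since these sizes lower every log2 ratio by 0.22. After correction for length, chosen after the data were seen, 154 of 9104 genes with a length were called, 78 higher in replicate 1 and 76 in replicate 2. Before it 469 of those genes had been called, and 96 were called both ways. The correction was fitted to these same data and removes the median ratio at each length, so a near-even split is largely built in.

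Among the 10 called genes with the largest ratios were Ibsp, at least 20.3-fold higher in replicate 1, Bglap, at least 11.4-fold, Mmp9, a matrix protease made by osteoclasts among other cells, with 167 and 1 reads (ratio 89.1, counting interval 15.8 to 3539.6), and Spp1, which encodes osteopontin, with 306 and 3 reads (ratio 54.4, 18.4 to 265). Ibsp lies on chromosome 5 from 104299171 to 104311469. Cfap77 had 225 and 0 reads (at least 40.0-fold). A new locus on chromosome 12 from 10898572 to 10898986 had 158 and 0 reads (at least 28.1-fold). Another on chromosome 3 from 58102571 to 58102996 had 117 and 0 reads (at least 20.8-fold). Each of these 3 adjoins a processed pseudogene that had more reads in replicate 2, so their ratios are uncertain. The pseudogene Gm5537 had 14 and 83 reads (ratio 0.0900, 0.0472 to 0.160) and adjoins the latter of these loci, so its ratio is uncertain too. Hgs had 63 and 3 reads (ratio 11.2, 3.66 to 55.8) and is uncertain, since another gene identifier with its symbol overlaps it. The mitochondrial polymerase gene Polg had 59 and 4 reads (ratio 7.87, 2.92 to 29.8).

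Longer transcripts took a larger share of replicate 1. The read-weighted median length of complete annotated models was 2063 nt in replicate 1 and 1777 nt in replicate 2. In genes with transcripts under 1000 nt the median log2 ratio of replicate 1 over replicate 2 was -0.32 (411 genes), and in those of 6000 nt or more it was 0.70 (202 genes). The ERCC spike-in RNAs read here, of 273 to 2022 nt, took 2.71% and 1.52% of all reads, a larger share of replicate 1 although they are short. ERCC-00002, the most read of them in both libraries, had 8894 and 2798 reads. The amount of spike-in RNA in each library was not examined, so these shares do not test the length trend.

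**Figure D3:**
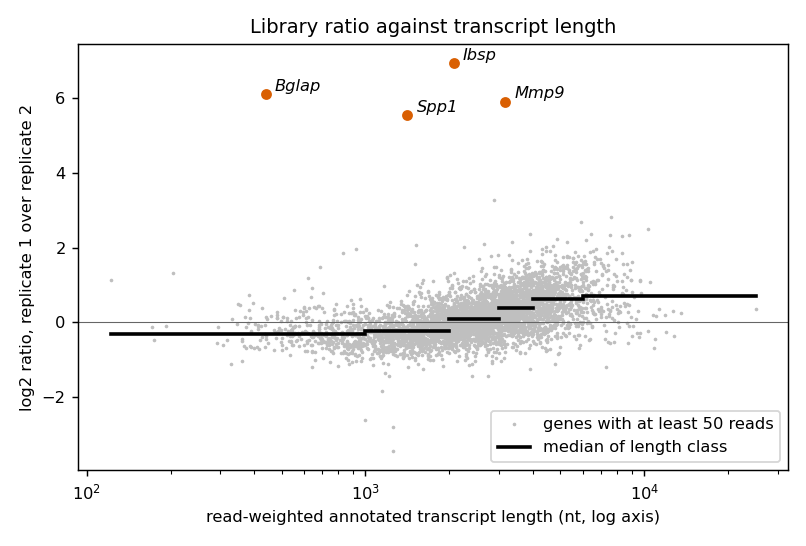
Log2 ratio of replicate 1 over replicate 2 against read-weighted annotated transcript length (nt, log axis), with 1 grey point per gene with at least 50 reads and black lines at the median of each length class. Medians go from -0.32 under 1000 nt to 0.70 from 6000 nt, and Ibsp, Bglap, Mmp9 and Spp1 (orange) lie far above them, with a pseudocount in place of counts of 0.

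Most reads fell on annotated transcripts. Complete annotated models took 71.7% ± 3.80 of endogenous reads (n = 2) and incomplete matches to them 8.37% ± 0.515. Models with new combinations of known splice sites took 8.44% ± 4.26 and those with at least 1 new splice site 7.19% ± 1.17. The rest fell on models that overlap a gene without matching its splicing (2.18% ± 0.0421), antisense models (1.84% ± 0.130) and intergenic models (0.253% ± 0.0233). The new-combination class held 11.5% of reads in replicate 1 (exact 95% interval 11.4 to 11.5) and 5.43% in replicate 2 (5.38 to 5.49), but the deposited classes differed for the same chain. Of 26284 intron chains found in both libraries, 466 were of that class in replicate 1 and of the new-site class in replicate 2, and 270 the reverse. Atp2a1 supplied 66744 of the 69590 reads on the former in replicate 1 and 30080 of 31763 in replicate 2. The reverse chains, which offset part of this, held 26548 and 7420 reads.

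By the deposited classes, several highly expressed muscle genes were read mainly on splice chains outside the annotation. Which junction of each chain departs from the annotation was not examined. Errors in aligning reads of these hybrid animals to mm10 were not tested as a source of such chains, so whether the chains are real transcripts is open. A chain of 22 exons held 66.5% and 75.4% of Atp2a1 reads in replicates 1 and 2, and one of 21 exons 24.5% and 16.1%. Chains of this kind held 40.8% and 20.8% of Myh4 reads, 58.1% and 55.1% of Aldoa reads, 63.4% and 67.7% of Srl reads and 96.3% and 96.4% of Oaz1 reads. For Bin1 the shares were 63.9% and 64.4%, for Ndrg2 53.1% and 47.9%, for Eno1 84.8% and 88.4%, and for Acta1 0.778% and 0.691%. These were the 10 new chains with the highest mean CPM in both libraries. In all, 41312 and 18408 new chains were found and 6892 were shared, 16.7% and 37.4% of each. With replicate 1 thinned to the depth of replicate 2, 5361 of 25295 and 18408 were shared. Of chains with 5 or more reads, 84.7% of those in replicate 1 and 97.2% of those in replicate 2 were found in the other library. For chains with 2 to 4 reads the shares were 34.8% and 75.8%, and for chains with 1 read 7.83% and 26.0%.

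Inclusion of cassette exons was measured in 96 events of 50 genes from a fixed list of alternatively spliced muscle genes. Of these, 45 exons were mostly included, 29 mostly skipped and 22 not resolved, 89 were annotated and 74 had a length that is a multiple of 3. Each exon was scored only against models joining its flanks directly, so alternative exons between the same flanks can both count as included. The Atp2a1 exon of 42 nt near the 3' end (chromosome 7, 126446545 to 126446586), which the adult form of the pump holds and the neonatal form lacks, was included in 77.7% ± 6.61 of reads (SD, n = 2). Its inclusion was 73.1% in replicate 1 and 82.4% in replicate 2 (two-sided Fisher exact test, adjusted p = 2.19e-295). No other event passed, but the others had a median of 42 informative reads in the library with fewer, and 18 of them differed by more percentage points.

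**Figure D4:**
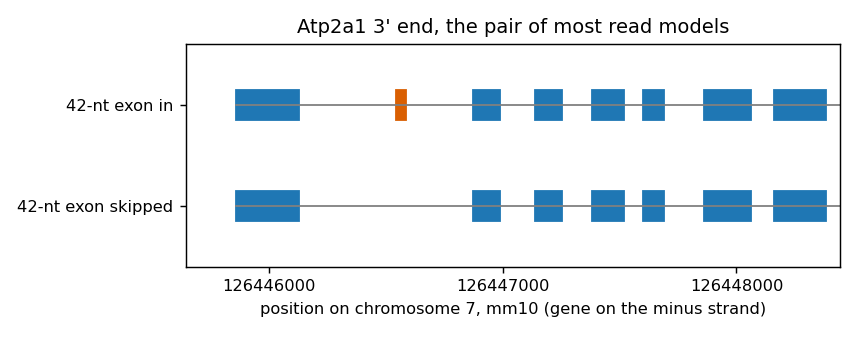
Exons of the pair of most read Atp2a1 models at the 3' end of the gene, to scale on chromosome 7 of mm10 (position in bases, gene on the minus strand). The orange exon of 42 nt lies between 126446545 and 126446586 and is joined in the upper model and skipped in the lower one.

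In other muscle genes, inclusion was 93.8% ± 0.734 for an exon of 42 nt in Ndrg2, 72.3% ± 0.903 for one of 72 nt in Bin1, a gene of T-tubule formation, 89.6% ± 1.14 for 45 nt in Gnas, 89.6% ± 1.84 for 45 nt in Mlf1 and 89.5% ± 3.37 for 113 nt in the capping protein gene Capzb. The Pdlim3 exon of 264 nt was included in 91.6% ± 3.44 of reads. Mybpc1, the slow myosin-binding protein gene, skipped exons of 54 and 59 nt, with inclusion of 10.7% ± 1.38 and 15.4% ± 0.165, and mostly held one of 42 nt (87.3% ± 1.37). Exons of 144, 138 and 96 nt in Mef2c were included in 94.1% ± 0.514, 89.5% ± 2.24 and 87.1% ± 1.000 of reads, and one of 21 nt in Mef2d in 87.1% ± 3.72. Inclusion was 94.0% ± 1.502 for 57 nt in Cacna1s, 80.4% ± 10.5 for 114 nt in Camk2b, 12.5% ± 7.58 for 79 nt in Tpm1 (on 28 informative reads in the library with fewer) and 6.26% ± 0.120 for 148 nt in Nfix. The Nfix exon of 123 nt lay at 47.2% ± 1.601 and was not resolved. Inclusion was 90.1% ± 1.71 and 91.5% ± 1.497 for Pkm exons of 117 and 123 nt, each on few reads, with 23 and 21 informative reads in the library with fewer. The one of 123 nt is not annotated. An Atp2a1 exon of 85 nt, also not annotated, was included at 92.5% ± 1.31 on only 61 informative reads in the library with fewer and is rare, since the pair of most read chains holds one of 81 nt with the same end. These values hold for reads with both flanking exons joined to the exon or to each other, which are few of the reads of genes such as Tpm1 and Pkm. With any spanning model counted, the Tpm1 and Pkm events did not meet the criteria, the Gnas and Mef2d values were 69.9% and 79.2%, the Camk2b value was 37.8%, and those of the Mef2c exons of 144 and 138 nt 62.1% and 34.3%. Mef2c had 72, 33 and 22 informative reads for the exons of 144, 138 and 96 nt in the library with fewer. Its exons of 144 and 138 nt lie between the same flanking exons and were scored against the same skipping reads, 12 and 4. Reads that hold the other exon of the pair are left out, so neither value is a share of all Mef2c reads.

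The most read annotated transcript held a median of 58.2% of the complete or new-junction reads over 51 genes of the same list, with exact 95% intervals above 50% in both libraries in 24 genes and below 50% in both in 20. The share was 98.4% ± 0.171 in Tpm1, 95.9% ± 0.359 in Tpm2, 95.3% ± 0.135 in Mybpc2 (n = 2), 92.8% ± 0.874 in Pkm, 59.8% ± 3.13 in Myl1, 58.2% ± 3.16 in Gnas, 37.4% ± 2.71 in Aldoa, 34.3% ± 5.23 in Ndrg2 and 25.04% ± 0.517 in Mybpc1. It was lowest in Atp2a1, at 0.0137% ± 0.00717, followed by Pdlim5 at 0.498% ± 0.704, Tnnt3 at 0.988% ± 0.0317, Lrrfip1 at 1.19% ± 0.635 and Bin1 at 1.36% ± 0.762. In Mybpc1, Aldoa and Ndrg2 the share was 98.8%, 95.6% and 92.8% among complete annotated models alone.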

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

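No test of a cause was run on the values in this part, which lie outside the main measurement and were looked at after the main results. Reads on the strand opposite to the ERCC spike-ins, which are made as single-stranded RNA, numbered 326 in replicate 1 and 113 in replicate 2, above the 3 reads that a count of 0 allows, and were 0.985% and 1.15% of spike-in reads.

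Loci assigned to no annotated gene, which include loci on the strand opposite to a gene, were also read above that limit. Of 13353 such loci, 2818 were read in both libraries, and 104 with at least 10 reads in each held 6502 reads in replicate 1 and 4304 in replicate 2. Intergenic models held only 3160 and 1479 reads in all, so most reads at these 104 loci were not intergenic. The most read by mean CPM lies on chromosome 9 from 77656524 to 77660127 on the minus strand, with 1041 and 1126 reads. The next lies on chromosome 17 from 39843013 to 39846245 on the same strand, with 1133 and 226 reads.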

How the results depend on the processing

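The length correction, the minor-form limits of 1% and 10% and the fibroblast list without Col1a1 were chosen after the results were seen, the other alternatives before. Over 122 results and 615 alternatives, 82 values of main results stayed within their spread or within 1.5 times their count and 27 moved. Among other values 434 stayed, 66 moved, 3 reversed in mean share, 2 became resolved and 1 ceased to be. The counts that stayed include settings that leave out a library. For a mean of 2 libraries such a setting lies within the SD by arithmetic, so it could not move and tests nothing. The Pearson's r and coefficient of variation given next belong to the main results. Pearson's r was 0.671 with a pseudocount of 0.1, 0.958 with 10, 0.890 with at least 10 reads, 0.914 in known genes and 0.886 without mitochondrial genes. The coefficient of variation was 0.263 with DESeq2 factors, 0.272 with library sizes, 0.263 and 0.249 with 1 and 50 reads or more, 0.257 in complete annotated models and 0.186 after the length correction. These have no spread of their own, so any change counts as moved. Between the libraries 349 genes were called with no read minimum, where more genes are tested, and 154 after the length correction.

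With complete annotated models alone, Myh4 held 40.7% and Myh1 45.2% of myosin heavy chain reads, fast genes 98.6% of troponin reads, and 18 cassette exons were left. Reversed in the mean, whatever the intervals in each library, were the joint shares of Myh4 with Myh1 (47.3%), Myh8 with Myh7 (30.4%) and Atp2a1 with Atp2a2 (8.28%). Without incomplete matches Myh8 held 1.96%. Complete models took 78.0% of reads and NNC models 5.84% among models with at least 5 reads, and incomplete matches 7.29% and 6.24% with at least 2 and 5. There were 42 exons with at least 50 reads and 169 with a minor form of 1%. Without NNC models, a class that takes in a different main Atp2a1 chain in each library, inclusion of its 42 nt exon was 56.0%. Shared new chains numbered 2571 and 908 with at least 2 and 5 reads in each library. Apart from shifts that follow from the reads or models left out, the cause was not tested. Leaving out a library gives the value of the other alone, with no test. No paired analysis was possible because there is 1 group. Depth limits genes under 10 reads, which had 2.56 and 4.79 CPM as the limit of a count of 0.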

Other observations

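Of the tests in this part, those of the cell mix, of length and depth for the bone genes and of the Gapdh copies were chosen after the result was seen. Splicing regulators summed to 1211 and 919.7 CPM, and with complete annotated models alone their mean fell from 1066 to 676 CPM. Rbm24, a muscle splicing factor, lay at 281 ± 6.35 CPM, Qk at 191 ± 39.6, Mbnl2 at 171 ± 78.9 and Hnrnpa1 at 89.9 ± 18.7, with Celf1 lowest of those with at least 10 reads in each library, at 17.2 ± 2.71, and Mbnl3 without a read. Mbnl2 held 80.1% ± 4.99 of the joint reads of Mbnl2 and Mbnl1, and 1 of 13 tested members, Celf2, was called higher in replicate 1, and not after correction for length. Cell cycle genes summed to 357 and 303 CPM with 0 of 10 called, led by the histone variant gene H2afz at 127 ± 5.85, Mcm2 at 47.5 ± 22.0, Mcm5 at 28.6 ± 6.55 and Pcna at 28.6 ± 11.5. Ccnb1 was lowest of those with at least 10 reads in each library, at 19.7 ± 1.43, while the proliferation marker Mki67 had 6 and 1 reads. In the list of non-coding RNAs, which summed to 4236 and 3399.5 CPM, H19 and Meg3 had at least 10 reads in each library, Malat1 had 53 and 9 reads and Xist 13 and 4, and of 6 tested members Meg3 and Malat1 were called higher in replicate 1, only Meg3 of them after correction for length.

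Longer transcripts took a larger share of replicate 1. A different mix of cells as the whole cause was examined in genes of the contractile, calcium and metabolic lists. Among these, 15 of 4 kb or more had a median log2 ratio 1.44 higher than 39 under 2 kb. A mix of muscle with other cells would leave muscle genes alike. The lists, however, also hold genes that other cells express, such as Actb and Acta2, and genes of particular fibre types, such as Myh2 and Myh7. Such genes can shift with the mix, so the comparison cannot decide the question. Shorter reads of the same molecules in replicate 2 stay open, since the share of incomplete matches in long genes was a median of 0.545 percentage points higher there, in 98 of 175 genes, between the bounds set beforehand. Which molecules entered each library was not tested, and no biological explanation was tested with 1 group.

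Bone genes were read in replicate 1. The length difference does not account for them, as the length-corrected log2 ratios of Ibsp and Bglap, the list members with at least 50 reads, were at least 4.37 and 3.79 with 3 reads allowed in replicate 2 (median 6.67 with a pseudocount in place of their 0 reads there), against 1.27 at the 99th percentile of 4349 genes. Depth does not either, since 60.8 reads of Ibsp would be expected in replicate 2 and none was found. Bone tissue carried along with the muscle of replicate 1 is a candidate source, since a second list of 16 bone cell genes, none on the first list, had 117 and 6 reads, 10.4-fold higher in CPM. Of its 4 tested members, Acp5 with 37 and 0 reads and Alpl with 19 and 0 were called. Smpd3 with 17 and 2 and Calcr with 8 and 2 were not, and the other members had too few reads to be tested. The osteoclast gene Ctsk, on neither list and picked outside the naming rule, had 74 and 9 reads. No biological explanation was tested.

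Gapdh had 43 and 26 reads, few for a glycolytic gene in muscle. Its reads may have been counted at copies of it, most of them processed pseudogenes, since the 16 copies closest to it in sequence averaged 479 reads each and the 51 less similar copies 0.255, a ratio of 1879.6. Within the 16 the reads were uneven. The copy Gm12671 alone had 2135 and 899 reads, while Gm10359, equally similar to Gapdh, had 19 and 9. Gm2574, Gm5138 and Gm2451, also among the 16, had none, so reads did not simply follow identity there. Gapdh and its copies together came to 4423 and 4081 CPM. Transcription of the copies themselves was not tested, nor was any biological explanation.

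The 3 features ranked first by ratio between libraries, with a pseudocount added to the counts, adjoin pseudogenes. The single-exon Cfap77 model on chromosome 2 from 28933429 to 28933610 shares 1 base with Gm13394, a copy of Gapdh that had 39 and 128 reads. Summed, the pair came to 225 and 204 CPM. For the new locus on chromosome 12 and Pgk1-rs7, with 35 and 131 reads, the sums were 164 and 209 CPM. For the new locus on chromosome 3 and Gm5537 they were 112 and 133 CPM.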
